A study of Mus musculus with 6 samples.

How the data were processed

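The measurements are 3' tag counts of polyadenylated RNA from 6 libraries of mouse tumor organoids, 3 with a scrambled guide (sgScr) and 3 with a guide against Prkci (sgPrkci). Libraries were made from 200 ng of total RNA with the Lexogen QuantSeq 3' FWD kit with optional molecular identifiers and sequenced as single-end reads on a NextSeq 500, per the labels' protocols. The genome build was GRCm38, per the submitters' processing notes. The aligner, the counting program, its strand setting, the handling of molecular identifiers and the gene annotation are not given in the sources used here.

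The deposited table holds 20756 genes by Ensembl identifier and 6 columns of CPM, reads scaled to the library total, made by the authors. Each column had the same sum, and 100% of its 124536 values were whole multiples of the value of 1 read in their column (tolerance 1e-06 of a read), so whole reads were recovered. Of the columns, 0 were left unmapped. Each library was matched to its group through its genotype label. That of the control is spelled sgScbr, its description is WT, and it was taken as the sgScr group that the series text names. The replicate numbers are names in accession order that pair nothing. The series text calls the libraries biological replicates, and how the cultures differed, or how many clones each guide population held, is not given in the sources used here. No 2 libraries agreed within sampling noise: the chi-square per degree of freedom of their reads was 1.63 to 3.18 within groups.

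Gene names, positions and exon overlaps came from GENCODE M21 by identifier, with no entry for 81 genes. Genes at 0 in all 6 samples numbered 1411. Genes with at least 1 CPM in at least 3 of the 6 samples, 12195 in all, were tested with limma (version 3.58.1, R 4.3.3) on log2(CPM + 1), with a variance trend and robust moderation, two-sided and with Benjamini-Hochberg adjustment, and called at an adjusted p under 0.05. All adjusted p-values of genes are from that test unless another tool is named. Of 35 gene lists fixed before the data were examined, 28 had at least 5 tested members and were tested against the other genes with camera, with a preset correlation of 0.01 and adjustment over the 28 lists. "Rose" and "fell" refer to genes past the threshold in limma. Chromosomes with at least 50 tested genes were tested as gene sets with camera in the same way, a test chosen after seeing the data. These sets held all tested genes of a chromosome. Medians and windows of chromosomes used only genes at a mean of at least 10 CPM.

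The genes to name were picked by a rule fixed before the data were examined. They included Prkci, Prkcz, Ulk1, Ulk2, Tbk1, Tmem173, Cgas, Irf3, Irf7 and Ifnb1, then the 10 genes with the largest and the 10 with the smallest log2 fold change among called genes at a mean of at least 5 CPM whose groups did not overlap, and up to 4 called members of each list with the lowest p. Clone identifiers were to be skipped among the top genes, and 0 were. Other members were named, after their values were seen, where a count was 5 or fewer, and so were Isg15, Hspa5, Muc2, the Y-linked genes beside Ddx3y, Xist and the genes of families added after seeing the data.

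Depth ran from 2141125 to 3048170 reads, so that 1 read was 0.328 to 0.467 CPM and a floor of 3 reads 0.984 to 1.40 CPM per library. For genes with 0 reads in a group the fold is a lower bound against 3 reads over that group, and for 1 to 3 reads the ratio has an exact 95% interval. Intervals and floors cover counting error only. One gene, Gm42418, which overlaps ribosomal RNA, took 10.1 to 12.4% of the reads, and mitochondrially encoded genes 11.7 to 13.9%.

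On simulated reads drawn from the means and depths of this comparison, with 200 of 12246 genes changed, the test recovered 50.7% of 1.5-fold, 80.6% of 2-fold and 90.9% of 4-fold changes, and 4.68% of its calls were unchanged genes. A further seeded list was raised 1.5-fold in the same reads, and its calls count among all calls. The simulation had a common dispersion, far fewer changed genes than the data and no chromosome shift, so these rates need not hold for the data. Alternatives were pseudocounts of 0.25 and 5 CPM, no filter or a filter at 5 CPM, TMM, median-of-ratios and quantile scaling, moderation without trend and robust weights, each library left out, other thresholds, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, and, for lists, an estimated correlation, fry and ranked camera. Unlike camera, fry tests a list against no change and not against the other genes, so a shift shared by all genes can make a list pass. Removing the median shift of each chromosome, and leaving Gm42418 and mitochondrial reads out of the totals, were added after seeing the data. The chromosome setting assigns each gene its chromosome's median shift as a known value, so its p-values leave out the error of that shift. Chromosomes with fewer than 50 genes at a mean of at least 10 CPM, such as the mitochondrial genome, took the median of all such genes, -0.08. The setting also recentres all genes, whose median log2 fold change went from -0.11 to -0.02, which moves calls toward higher by construction.

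The 3' tags of some named genes fall where annotated exons overlap, so their reads are uncertain. Another gene's exons overlap on the same strand for Uba7, Gbp7, Tapbp, Ctsd, Top2a, Mcm7, Gclm, Rps3 and Trf. They overlap on the opposite strand, which matters if counting ignored strand, for Cgas, Irf3, Irf7, Il1a, Krt90, Ifi35, Psme1, Ikbke, Sqstm1, Bnip3, Prom1, Sox17, Ccnd1, Sox4, Anxa2, Vil1, Tff1, Bcas1, Mmp7, Ptgs1, Lama3, Col4a2, Prc1, Cdkn1a, Atf5, Shmt2, Ndrg1, Hmgcs1, Cox4i1, mt-Nd5 and Junb. Near-identical copies can share reads for H2-D1, Gbp7, Gstm1, Gsta3, Gsta4, Sprr1a and the ribosomal protein genes.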

Results

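Gene expression was measured by 3' tag sequencing in mouse tumor organoids, which are 3-dimensional cultures grown here from a liver metastasis of an intestinal tumor on the C57BL/6 background. One organoid population carried a guide RNA against Prkci, the gene of the atypical protein kinase C lambda/iota (sgPrkci), and the other a scrambled guide (sgScr), with 3 libraries of each that the series describes as biological replicates. The organoids received no treatment and were harvested 72 h after plating. Depth was 2982916, 3048170 and 2821908 reads in sgScr replicates 1, 2 and 3, and 2651355, 2141125 and 2815760 reads in sgPrkci replicates 1, 2 and 3. Between 14223 and 15380 genes had at least 1 read in a library. Pearson's r of log2(CPM + 1) across genes was 0.981 to 0.984 between libraries of 1 group and 0.947 to 0.954 between groups. CPM stands for the reads of a gene scaled to the library total. Values below are means ± SD of 3 libraries in CPM, and log2 fold changes are sgPrkci minus sgScr on the log2(CPM + 1) scale, which understates the change of low genes. Positions are those of the gene in GENCODE M21 on GRCm38.

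The comparison of sgPrkci with sgScr asks which transcripts differ between organoids with PKC lambda/iota targeted and the control organoids. The series title ties loss of PKC lambda/iota to ULK2 and an interferon response. How many independent edits the libraries of a guide represent is not given in the sources used here. All p-values of genes and lists therefore measure spread between libraries. They cannot separate the guide from other differences between the organoid populations. Prkci mRNA (ENSMUSG00000037643, chromosome 3, 30995747 to 31052959) was at 54.9 ± 8.6 CPM in sgScr and 52.4 ± 4.99 CPM in sgPrkci (log2 fold change -0.06, SE 0.13, adjusted p = 0.77). The guide's position is not given in the sources used here, and a 3' tag outside the edited part does not report the edit, so these reads do not check the labels. Ulk2 (chromosome 11, 61775649 to 61855073), which encodes a kinase that starts autophagy, fell from 24.9 ± 2.67 to 15.1 ± 1.95 CPM (log2 fold change -0.69, SE 0.18, adjusted p = 0.003). Tmem173 (chromosome 18, 35733679 to 35740554), which encodes the DNA-sensing adaptor STING, fell from 36.4 ± 1.56 to 22.1 ± 2.15 CPM (log2 fold change -0.70, SE 0.15, adjusted p = 0.00058). Among the genes fixed for the text with them, Prkcz, the other atypical protein kinase C, was at 5.64 ± 0.706 CPM in sgScr and 3.38 ± 1.18 CPM in sgPrkci (adjusted p = 0.095). Ulk1 had a log2 fold change of 0.24 (adjusted p = 0.43) and Tbk1 of -0.23 (adjusted p = 0.22). For Cgas it was -0.60 (adjusted p = 0.1), for Irf3 -0.07 (adjusted p = 0.8) and for Irf7 -0.29 (adjusted p = 0.57), so that none of these 5 passed in limma with all 6 libraries. Ifnb1 was not among the 20756 genes listed, so it was not analysed here. The call of Ulk2 ended with DESeq2 and when the median shift of each chromosome was removed, where its log2 fold change was -0.29. The gene Cgas passed without sgPrkci replicate 3 (log2 fold change -0.95, adjusted p = 0.015). Under 5 of the scaling and count-model alternatives the signs of Prkci and Irf3 turned, with log2 fold changes of at most 0.063.

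On the log2(CPM + 1) scale the largest rise among the named genes was that of Cxcl5 (chromosome 5, 90759360 to 90761624), a chemokine that attracts neutrophils, which rose from 1.91 ± 0.467 to 106 ± 8.4 CPM (log2 fold change 5.21, SE 0.19, adjusted p = 3.5e-19). The mannose receptor gene Mrc1 rose from 1.12 ± 0.476 to 66 ± 7.36 CPM and the urotensin 2 gene Uts2 from 4.28 ± 0.558 to 131 ± 4.31 CPM. Nexmif rose from 0.801 ± 0.726 to 40.9 ± 7.26 CPM and the interleukin 1 alpha gene Il1a from 1.38 ± 0.967 to 48.8 ± 6.45 CPM. Kif5c, a kinesin gene, rose from 3.64 ± 0.863 to 63.9 ± 4.48 CPM and the receptor phosphatase gene Ptprz1 from 2.82 ± 1.02 to 50.7 ± 6.73 CPM. The Y-linked RNA helicase gene Ddx3y had 0 reads in sgScr and 149 in sgPrkci, at least 57.8-fold higher against a floor of 3 reads over the group. Slc39a4, a zinc importer gene, had 1 read in sgScr and 165 in sgPrkci, a ratio of 192 by depth with a 95% counting interval of 34.0 to 7629. The integrin gene Itga2 had 2 and 110 reads, a ratio of 64.0 (17.3 to 535). Among the deepest falls, the collagen gene Col8a1 (chromosome 16, 57624258 to 57754737) fell from 143 ± 26.1 to 2.34 ± 0.602 CPM (log2 fold change -5.43, SE 0.18, adjusted p = 1.3e-19). The receptor phosphatase gene Ptprb fell from 117 ± 3.15 to 2.22 ± 0.692 CPM, and the insulin-like growth factor binding protein gene Igfbp4 from 111 ± 6.8 to 4.07 ± 1.5 CPM. The keratin genes Krt90 and Krt4 fell from 204 ± 7.47 to 6.13 ± 2.08 CPM and from 295 ± 11.8 to 14.9 ± 2.87 CPM, and the cornifelin gene Cnfn from 76.2 ± 13 to 1.69 ± 0.492 CPM. Prrg1 fell from 22 ± 1.97 to 0.526 ± 0.206 CPM. Serpinb11 had 129 reads in sgScr and 0 in sgPrkci, at least 37.0-fold lower. Crip1 had 144 and 1 reads, a ratio of 124 of sgScr over sgPrkci (21.9 to 4922). The monoamine oxidase gene Maoa had 117 and 1 reads, a ratio of 101 (17.7 to 4005).

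Of 12195 genes tested with limma, 3882 changed at an adjusted p under 0.05, of which 1387 (35.7%) were higher and 2495 (64.3%) lower in sgPrkci. At least 2-fold changes were seen for 346 higher and 474 lower genes. The 3 libraries of one group lay apart from the 3 of the other for 5247 genes (43.0%), where chance gives 10%. This split depended on the scaling: the median log2 fold change of all genes was -0.11 on the CPM scale and -0.02 with TMM factors, under which 1918 genes (51.4%) were higher and 1816 lower. Quantile normalization gave 1741 higher and 1893 lower genes, median-of-ratios factors 1921 and 1822, edgeR on the reads 1939 and 1815, and DESeq2 1422 and 1118.

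**Figure D1:**
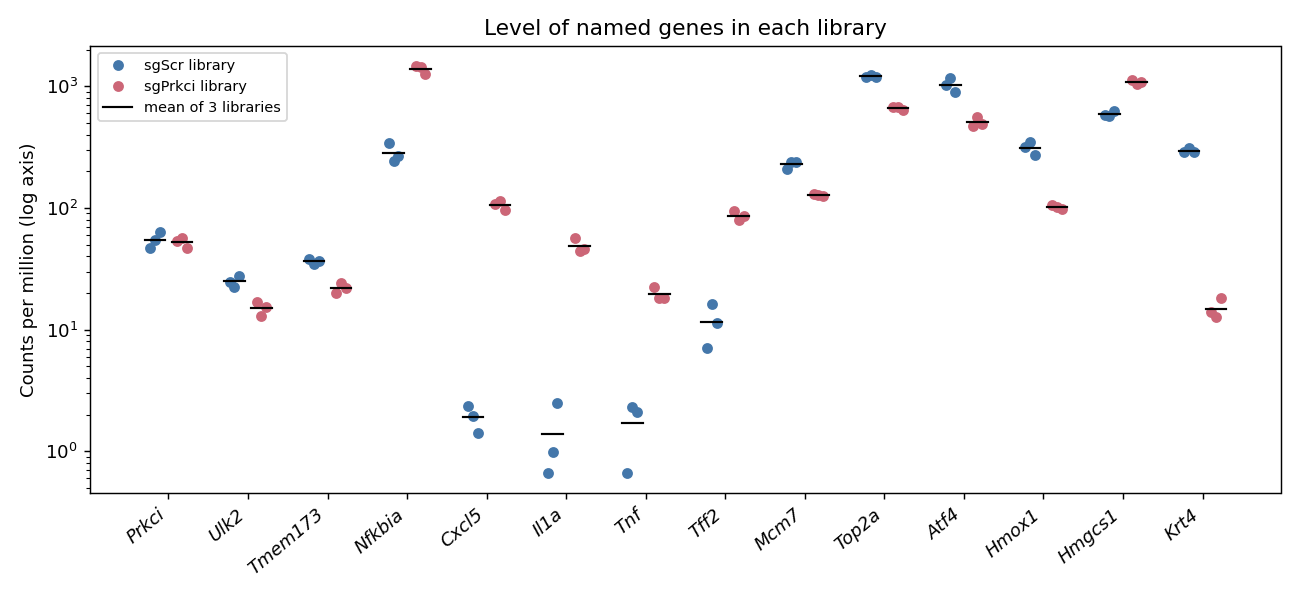
Level of 14 named genes in each library, in CPM on a log axis, with sgScr libraries in blue, sgPrkci libraries in red and a line at the mean of 3 libraries. Cxcl5, Il1a, Tnf, Tff2 and Nfkbia lay higher in every sgPrkci library than in any sgScr library, Krt4, Hmox1, Atf4, Top2a and Mcm7 lower, and Prkci overlapped.

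Genes of whole chromosomes were lower or higher together. Relative to all genes, the median of genes at a mean of at least 10 CPM was -0.31 on chromosome 11, -0.28 on chromosome 15 and -0.20 on chromosome 8, and it was 0.27 on chromosome 1. Camera called 7 of 20 chromosomes, with 8, 11 and 15 lower and 1, 4, 5 and 12 higher, and 4 of them (1, 8, 11 and 15) with an estimated correlation. Chromosomes 8, 11 and 15 held 16.9% of the tested genes, 835 (33.5%) of the lower calls and 79 (5.7%) of the higher calls. Reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty numbered 1 in the 3 sgScr libraries and 336 in the 3 sgPrkci libraries. With the chromosome medians removed, 1608 genes were higher and 1623 lower, in a setting that also moved the median log2 fold change of all genes to -0.02. Of the genes picked by the rule that fell, Ulk2, Wwc1, Sqstm1, Wipi1, Canx, Top2a, Hmmr, Ifi35, Trim25, Uqcrq, Rpl38, Krt14 and Igfbp4 lie on chromosome 11, Atf4, Rpl8, Cyc1, Krt4 and Krt90 on chromosome 15, and Hmox1, Cdt1 and Cox4i1 on chromosome 8. Falling genes that were named after their values were seen are not in this list, and some may lie there too.

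**Figure D2:**
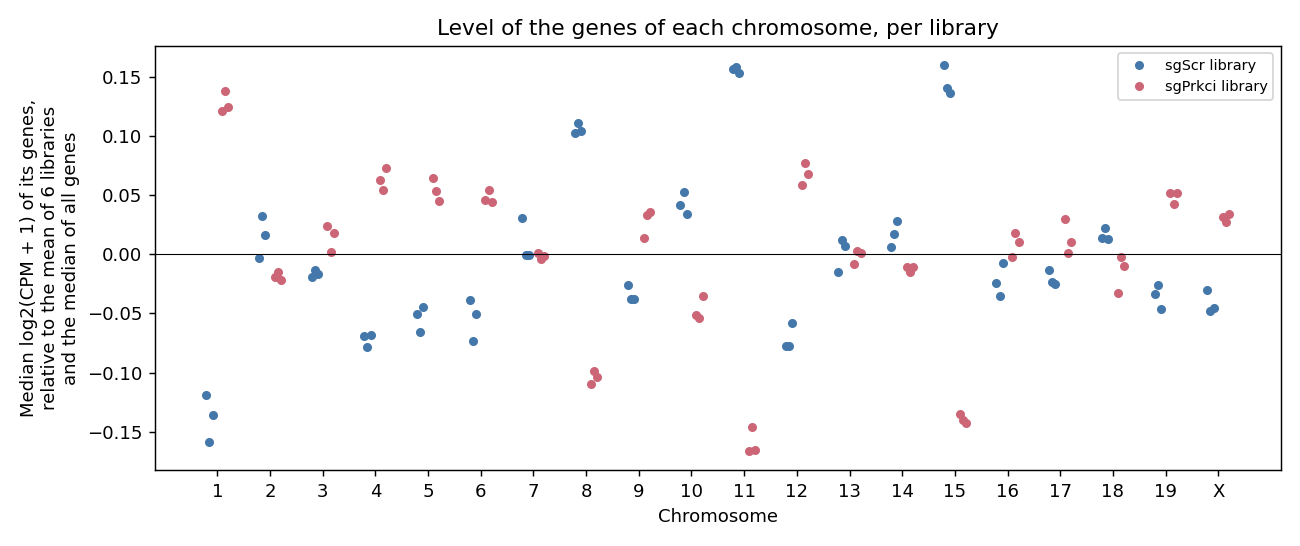
Median over the genes of each chromosome (mean of at least 10 CPM) of log2(CPM + 1), relative to the mean of the 6 libraries and to the median of all genes, with 1 point per library, blue for sgScr and red for sgPrkci. On chromosome 11 the sgScr libraries lay between 0.153 and 0.158 and the sgPrkci libraries between -0.166 and -0.146.

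Inflammatory gene lists were higher relative to other genes with the preset correlation. Of 14 tested chemokine and cytokine genes 7 rose and 2 fell (camera adjusted p = 1.9e-06, and adjusted p = 0.08 with an estimated correlation). Beside Cxcl5 and Il1a, the neutrophil chemokine gene Cxcl1 rose from 4.92 ± 2.85 to 40.8 ± 2.51 CPM and the tumor necrosis factor gene Tnf from 1.7 ± 0.894 to 19.5 ± 2.36 CPM. Il1rn and Il33 were the 2 that fell, by 0.93 and 0.59 on the log2 scale. Of 21 genes of the NF-kappaB pathway and its targets 12 rose and 1, Sqstm1, fell (camera adjusted p = 3.7e-09, and adjusted p = 0.11 with an estimated correlation). Nfkbia, the NF-kappaB inhibitor, rose from 283 ± 51.6 to 1389 ± 106 CPM (log2 fold change 2.30, SE 0.10, adjusted p = 4.1e-13). The target gene Tnip3 rose from 5.8 ± 1.43 to 46.7 ± 4.12 CPM. Birc3 rose from 12.9 ± 0.72 to 44.2 ± 4.99 CPM and Ier3 from 615 ± 85.7 to 1774 ± 80.5 CPM. Adjusted over the list alone, the counts were again 7 and 2, and 12 and 1. Of 26 dissociation and immediate early genes 11 rose and 1, Dnajb1, fell (camera adjusted p = 0.00044, and adjusted p = 0.18 with an estimated correlation). Egr1 rose from 37.8 ± 3.17 to 64 ± 3.77 CPM and Junb from 240.0 ± 10.2 to 348 ± 31.4 CPM. These counts were also 11 and 1 adjusted over the list alone. Dnajb1 did not pass with TMM, median-of-ratios or quantile scaling.

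Interferon-stimulated genes moved in both directions. Of 33 tested members 4 rose, 7 fell and 22 did not pass, with a median log2 fold change of -0.16 (camera adjusted p = 0.97, and adjusted p = 0.98 with an estimated correlation). Mx1, an antiviral GTPase gene, rose from 2.59 ± 1.53 to 7.07 ± 0.745 CPM. Sp110, Samd9l and Tor3a were the other 3 that rose. Uba7, which encodes the enzyme that activates ISG15, fell from 5.21 ± 0.82 to 1.63 ± 1.29 CPM. Ifi35 fell from 10.7 ± 1.77 to 4.77 ± 2.79 CPM and Trim25, the ligase for RIG-I, from 50.8 ± 2.16 to 36.1 ± 1.54 CPM. Isg15 itself fell by 0.97 on the log2 scale. Of 11 interferon-gamma induced genes 2 rose and 3 fell (camera adjusted p = 0.57, and adjusted p = 0.61 with an estimated correlation). Irf8 rose from 12.7 ± 1.22 to 29.5 ± 3.53 CPM and Gbp7 from 2.13 ± 1.66 to 5.81 ± 0.42 CPM. Wars, Psme1 and Irgm1 fell by 0.60, 0.38 and 0.93. Of 17 MHC class I presentation genes 2 rose and 2, Psme1 and Canx, fell (camera adjusted p = 0.63, and adjusted p = 0.65 with an estimated correlation). H2-D1 rose from 210.2 ± 21 to 259 ± 17.9 CPM and Tapbp from 46.1 ± 9.96 to 62.7 ± 5.82 CPM. Of 26 genes of nucleic acid sensing and TBK1-IRF3 signalling 6 rose and 6 fell (camera adjusted p = 0.83, and adjusted p = 0.87 with an estimated correlation). Aim2, a DNA sensor gene, rose from 65 ± 8.46 to 117 ± 3.79 CPM. Trim56 rose from 103 ± 15.2 to 159 ± 4.04 CPM and the kinase gene Ikbke from 2.27 ± 1.53 to 8.36 ± 1.08 CPM. Samhd1, which limits nucleotide supply to viruses, fell from 53.4 ± 1.2 to 29.6 ± 1.42 CPM. Of 10 interferon and receptor genes 2 rose (camera adjusted p = 0.029, and adjusted p = 0.23 with an estimated correlation). They were Ifngr2, from 26.6 ± 2.78 to 43.4 ± 2.81 CPM, and Ifne, from 1.01 ± 0.317 to 3.35 ± 2.27 CPM. In the order given, the counts adjusted over the list alone were 4 and 7, 3 and 3, 2 and 2, 6 and 6, and for the interferon and receptor genes 1 that rose. The interferon and receptor list lost its call with edgeR, DESeq2, a filter at 5 CPM, chromosome medians removed or without sgScr replicate 2. With chromosome medians removed 3 interferon-stimulated genes rose and 4 fell, and of the interferon-gamma list 4 rose and 1 fell. Of MHC class I genes 4 then rose and 0 fell in limma (1 was lower at an unadjusted p under 0.05), of sensing genes 5 rose and 4 fell and of interferon and receptor genes 3 rose. That setting ended the calls of Ifi35, Trim25, Psme1, Canx and Ifne. In it the log2 fold change of the gene Ifi35 was -0.72 (adjusted p = 0.057) and that of the gene Trim25 -0.082 (adjusted p = 0.68). Psme1 stayed at -0.30 (adjusted p = 0.073) against -0.38 in the main fit, and Ifne at 0.92 (adjusted p = 0.075) against 0.97. Plain eBayes moderation ended those of Ifi35, Psme1, H2-D1, Tapbp, Canx and Ifne, and TMM, median-of-ratios and edgeR those of Psme1 and Canx. A pseudocount of 0.25 CPM ended that of Ifne. Ifi35, Trim25, Uba7, Wars, Psme1, Canx and Ifne lost theirs with DESeq2, where 0 interferon-stimulated genes fell, with 6 lower at an unadjusted p under 0.05 and 6 that fell with edgeR. Calls also ended without sgScr replicate 1 for Psme1, without sgScr replicate 2 for H2-D1, Tapbp, Canx, Psme1 and Ifne, without sgScr replicate 3 for Canx, Wars and Ifne, without sgPrkci replicate 1 for Tapbp and Ifne, without sgPrkci replicate 2 for H2-D1, Canx and Ifne, and without sgPrkci replicate 3 for Psme1 and Canx.

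Genes of cell division fell together. Of 30 DNA replication genes 24 fell and the other 6 did not pass, with a median log2 fold change of -0.72 (camera adjusted p = 2.4e-09, and adjusted p = 0.18 with an estimated correlation). Mcm7, of the replicative helicase, fell from 229 ± 16.3 to 128 ± 3.5 CPM (log2 fold change -0.84, SE 0.09, adjusted p = 1.8e-08). The licensing factor gene Cdt1 fell from 65.3 ± 5.47 to 30.9 ± 4.31 CPM. The ribonucleotide reductase gene Rrm1 fell from 117 ± 10.5 to 64.8 ± 2.33 CPM. Of 30 G2/M and mitotic genes 22 fell and the other 8 did not pass, with a median of -0.42 (camera adjusted p = 1.5e-08, and adjusted p = 0.18 with an estimated correlation). Top2a, the topoisomerase of dividing cells, fell from 1204 ± 30.9 to 661 ± 24.1 CPM. The mitotic genes Cenpe fell from 442 ± 25.4 to 263 ± 14.5 CPM, Prc1 from 254 ± 11.3 to 147 ± 14.6 CPM and Hmmr from 157 ± 6.9 to 99 ± 5.26 CPM. Of 21 p53 target genes 6 rose and 2 fell, with a median of -0.04 but a mean 0.26 above that of other genes (camera adjusted p = 0.044, and adjusted p = 0.23 with an estimated correlation). Pmaip1, a cell death gene, rose from 71.2 ± 5.06 to 186 ± 14.5 CPM. The antiproliferative gene Btg2 rose from 27.7 ± 0.447 to 84.1 ± 6.83 CPM and the cell cycle inhibitor gene Cdkn1a from 357 ± 49.98 to 571 ± 41.7 CPM. Ccnd1 (cyclin D1) fell from 991 ± 139 to 599.6 ± 49.9 CPM. Adjusted over the list alone 27 replication genes and 27 mitotic genes fell, and 6 p53 targets rose and 2 fell. The mitotic count was 14 with DESeq2 and with plain eBayes moderation. The p53 list lost its call with quantile normalization, with ranked camera and without sgScr replicate 1, sgScr replicate 2 or sgPrkci replicate 3.

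Lists of oxidative and amino acid stress genes were lower relative to other genes with the preset correlation. Of 25 NRF2 target genes 13 fell and 2 rose, Gsta3 and Gsta4 (camera adjusted p = 0.00055, and adjusted p = 0.16 with an estimated correlation). The heme oxygenase gene Hmox1 fell from 312 ± 37.8 to 101 ± 3.8 CPM (log2 fold change -1.61, SE 0.09, adjusted p = 6.6e-14). The subunit genes of glutathione synthesis fell, Gclc from 278 ± 15.6 to 105 ± 4.78 CPM and Gclm from 232 ± 4.49 to 107 ± 5.76 CPM. The glutathione transferase gene Gstm1 fell from 62.7 ± 1.48 to 21.8 ± 1.42 CPM. Of 30 genes of the unfolded protein and integrated stress responses 12 fell and 3 rose (camera adjusted p = 0.013, and adjusted p = 0.47 with an estimated correlation). Those that fell included Atf4, the transcription factor of amino acid stress, from 1025 ± 131 to 506 ± 46.9 CPM, and Atf5, from 158 ± 10.9 to 66.6 ± 10.6 CPM. The mitochondrial folate pathway genes Shmt2 and Mthfd2 fell from 101 ± 8.19 to 40.5 ± 1.67 CPM and from 261 ± 16.7 to 134 ± 5.58 CPM. The 3 that rose were Pdia6, Xbp1 and Ddit4. Hspa5, the main chaperone of the unfolded protein response, had a log2 fold change of -0.08 (adjusted p = 0.41). Counts adjusted over the list alone were 13 falls and 2 rises for NRF2 targets and 14 falls and 3 rises for stress genes. The stress response list did not pass with ranked camera, and 6 of its genes rose with TMM, median-of-ratios or edgeR scaling.

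Hypoxia and sterol lists were higher relative to other genes with the preset correlation. Of 30 hypoxia and glycolysis genes 10 rose and 3 fell (camera adjusted p = 0.00018, and adjusted p = 0.16 with an estimated correlation). Egln3, an oxygen-sensing hydroxylase gene, rose from 463 ± 1.16 to 1167 ± 40.1 CPM and Ndrg1 from 539 ± 8.52 to 852 ± 37.2 CPM. Ero1l rose from 733 ± 25.9 to 1138 ± 32.1 CPM and the glycolysis regulator gene Pfkfb3 from 27.4 ± 2.39 to 55.1 ± 5.3 CPM. Slc16a3, Pfkl and Eno1 were the 3 that fell. Of 25 cholesterol synthesis genes 10 rose and the other 15 did not pass (camera adjusted p = 0.00018, and adjusted p = 0.11 with an estimated correlation). Hmgcs1 rose from 589 ± 29.3 to 1084 ± 36.8 CPM. Hsd17b7 rose from 56.6 ± 8.84 to 91.4 ± 5.59 CPM and Msmo1 from 477 ± 14.9 to 659.9 ± 31.5 CPM. Of 9 genes of the mitochondrial genome 3 rose (camera adjusted p = 0.0064, and adjusted p = 0.37 with an estimated correlation). They were mt-Cytb, from 2711 ± 59.5 to 3517 ± 426 CPM, mt-Nd5, from 900.2 ± 55.4 to 1102 ± 174 CPM, and mt-Rnr1. Nuclear genes of oxidative phosphorylation had 2 of 37 that rose and 9 that fell (camera adjusted p = 0.69, and adjusted p = 0.77 with an estimated correlation). Uqcrq fell from 311 ± 28.4 to 188 ± 15 CPM, and Cyc1, Cox4i1 and Uqcrc1 fell with it. Of 40 ribosomal protein genes 9 fell and 2, Rplp0 and Rps16, rose (camera adjusted p = 0.69, and adjusted p = 0.69 with an estimated correlation). Rpl8 fell from 940.0 ± 69.2 to 621 ± 28.6 CPM and Rps3 from 858 ± 35.5 to 601 ± 15.3 CPM. For hypoxia 10 rose and 4 fell adjusted over the list alone, and 11 cholesterol genes and 4 of the mitochondrial genome rose. The counts of rises and falls were then 2 and 9 for oxidative phosphorylation and 2 and 9 for ribosomal proteins. The mitochondrial list lost its call with quantile normalization and with fry, and the oxidative phosphorylation counts were 6 and 6 with TMM. The oxidative phosphorylation and ribosomal lists passed with fry, which does not compare with other genes. Their mean differences from other genes were 0.031 and 0.038 in the main fit. With chromosome medians removed, 17 hypoxia genes rose, the calls of Cyc1, Cox4i1 and Rpl38 ended, and 4 oxidative phosphorylation and 2 ribosomal genes fell. In that setting 6 mitochondrial genome genes rose, but they had the median of all genes removed, not a median of their own. Plain eBayes moderation ended the calls of mt-Cytb, mt-Nd5, mt-Rnr1, Rpl38 and Rplp0, DESeq2 that of Cyc1 and quantile normalization that of mt-Rnr1. The calls of mt-Nd5 ended without sgScr replicate 2 or 3 and without sgPrkci replicate 1 or 2, and that of mt-Rnr1 without any 1 of the libraries but sgScr replicate 1.

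Of 13 goblet cell genes, which mark mucus-secreting cells, 8 rose and 1, Fer1l6, fell (camera adjusted p = 1.9e-06, and adjusted p = 0.08 with an estimated correlation). The trefoil factor gene Tff2 rose from 11.6 ± 4.69 to 86.3 ± 7.08 CPM (log2 fold change 2.86, SE 0.20, adjusted p = 3.1e-09) and Tff1 from 563 ± 32.4 to 1101 ± 57.4 CPM. Spink4 rose from 1.24 ± 0.695 to 25.6 ± 6.74 CPM and Bcas1 from 7.75 ± 3.79 to 63.2 ± 4.42 CPM. The intestinal mucin gene Muc2 had a log2 fold change of -0.34 (adjusted p = 0.55). Of 19 intestinal stem cell genes 8 rose and 3 fell (camera adjusted p = 0.017, and adjusted p = 0.18 with an estimated correlation). Prom1 rose from 11 ± 1.42 to 66.5 ± 0.414 CPM and Cd44 from 1006 ± 132 to 1649 ± 159 CPM. Slc12a2 rose from 203 ± 10.3 to 298 ± 10.3 CPM and Ephb2 from 19.6 ± 3.07 to 37.8 ± 0.918 CPM. Cdca7, Axin2 and Tnfrsf19 were the 3 that fell. Of 18 WNT target genes 4 rose and 6 fell (camera adjusted p = 0.82, and adjusted p = 0.87 with an estimated correlation). Sox17 rose from 82.9 ± 2.69 to 144 ± 2.21 CPM and Sox4 from 149 ± 9.19 to 230.3 ± 16.1 CPM, and Ccnd1 fell. Of 28 fetal, regenerative and YAP target genes 11 rose and 8 fell (camera adjusted p = 0.088, and adjusted p = 0.37 with an estimated correlation). Anxa2 rose from 3421 ± 113 to 6217 ± 428 CPM and Clu from 54.7 ± 6.76 to 125 ± 3.96 CPM. The YAP target gene Amotl2 fell from 34 ± 3.73 to 12.2 ± 2.34 CPM. Of 8 enterocyte genes 2 rose and 2 fell (camera adjusted p = 0.82, and adjusted p = 0.87 with an estimated correlation). Krt20 rose from 2.57 ± 3.04 to 21.8 ± 2.75 CPM and Vil1 from 55.6 ± 3.28 to 93.1 ± 14.1 CPM. Apoa1 fell from 7.8 ± 7.46 to 0.651 ± 0.42 CPM, and Cdhr2 fell with it. Of 14 squamous genes 4 rose and 4 fell, with a median of 0.09 and a mean difference from other genes of -0.38 (camera adjusted p = 0.97, and adjusted p = 0.98 with an estimated correlation). Krt14 fell from 91 ± 10.1 to 10.7 ± 3.93 CPM beside Cnfn, Krt16 and Lor. Pkp1 and Sprr1a rose, from 66.3 ± 5.17 to 103 ± 13.6 CPM and 39.3 ± 3.39 to 64.3 ± 4.96 CPM, beside Ivl and Dsp. Of 14 genes of mesenchymal transition and matrix 5 rose and the other 9 did not pass (camera adjusted p = 0.00044, and adjusted p = 0.16 with an estimated correlation). Among those that rose were the laminin gene Lama3, from 57 ± 1.92 to 99.7 ± 7.03 CPM, Col4a2, Plaur and the epithelial gene Epcam, from 551 ± 14.7 to 771 ± 63.9 CPM. Rises and falls adjusted over the list alone were 9 and 2 for goblet, 8 and 3 for stem, 4 and 6 for WNT, 12 and 9 for fetal, 2 and 2 for enterocyte, 4 and 4 for squamous and 5 rises for matrix genes. The stem list did not pass with ranked camera, and the fetal list passed with edgeR, DESeq2 and chromosome medians removed. Without the filter on low values 11 enterocyte genes fell and the list passed (adjusted p = 0.0083). The squamous list passed with fry. The call of Apoa1 ended with edgeR, a pseudocount of 5 CPM, plain eBayes moderation and without sgPrkci replicate 2, and that of Cdhr2 with quantile normalization, DESeq2 and plain eBayes moderation. Calls also ended without sgScr replicate 2 or sgPrkci replicate 1 for Col4a2, and for Cdhr2 without sgScr replicate 1 or 2 or sgPrkci replicate 1 or 3.

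Lists with fewer than 5 tested members had no set test. Of 3 Paneth cell genes Itln1 rose and Mmp7 and Nupr1 fell. Of 2 enteroendocrine genes Cpe rose from 129.6 ± 7.37 to 289 ± 14.7 CPM. Of 4 tuft cell genes Cd24a rose from 483 ± 18.5 to 609.5 ± 41.6 CPM and Ptgs1 fell from 292 ± 23.9 to 242 ± 14.6 CPM. Of markers of cell types outside the epithelium, 2 immune genes were tested and Cd68 rose from 5.86 ± 1.32 to 10.1 ± 1.87 CPM. Of 3 hepatocyte genes Apoa1 fell and Trf rose. Trf had 1 read in sgScr and 38 in sgPrkci, a ratio of 44.2 (7.47 to 1792). The fibroblast and endothelial list and the erythroid list had 0 members above the filter on low values. Adjusted over the list alone these counts were the same. The call of Cd68 ended with DESeq2 and without sgScr replicate 2 or 3 and sgPrkci replicate 1 or 3, and that of Ptgs1 without sgScr replicate 1 or 2 or sgPrkci replicate 1 and with TMM, median-of-ratios, edgeR, DESeq2, plain eBayes moderation or chromosome medians removed. That of Cd24a ended with plain eBayes moderation.

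Polarity, autophagy and lysosome genes changed in both directions. Of 20 genes of the atypical protein kinase C and polarity complexes 3 rose and 5 fell (camera adjusted p = 0.69, and adjusted p = 0.69 with an estimated correlation). Mpp5 rose from 146 ± 13.9 to 201 ± 17.6 CPM, and Wwc1, which encodes KIBRA, fell from 223 ± 4.44 to 127 ± 3.6 CPM. The scaffold and autophagy receptor gene Sqstm1 fell from 382 ± 12.4 to 251 ± 26.8 CPM and Ect2 from 118 ± 14.6 to 78 ± 2.97 CPM. Of 39 ULK complex and autophagy genes 5 rose and 6 fell (camera adjusted p = 0.58, and adjusted p = 0.61 with an estimated correlation). Ulk2, Sqstm1 and Wipi1 fell and Bnip3 rose from 565 ± 26.4 to 780.0 ± 14.4 CPM. Of 29 lysosome genes 3 rose and 2 fell (camera adjusted p = 0.056, and adjusted p = 0.37 with an estimated correlation). The cathepsin genes Ctsh and Ctsd rose from 303 ± 21.8 to 439 ± 21.7 CPM and from 145 ± 11.4 to 201 ± 9.39 CPM, and Npc2 from 161 ± 15.5 to 218 ± 14.5 CPM. Adjusted over the list alone the counts were 3 and 5, 5 and 6, and 3 and 1. With chromosome medians removed 10 autophagy genes rose and 0 fell in limma (2 were lower at an unadjusted p under 0.05), against 6 and 3 with TMM and with edgeR. The sign of Wipi1 turned with the medians removed, and its call also ended with TMM, median-of-ratios, edgeR, DESeq2, plain eBayes moderation and without sgPrkci replicate 2. Removing those medians also ended the call of Sqstm1, and 4 polarity genes then rose and 2 fell. The lysosome list passed with them removed (adjusted p = 0.011), with TMM (adjusted p = 0.028), median-of-ratios, DESeq2, ranked camera or no filter on low values. It also passed with Gm42418 and mitochondrial reads left out of the totals and without sgScr replicate 1 or sgPrkci replicate 3. The polarity list passed with fry.

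With the preset correlation of 0.01, camera called 15 of 28 tested lists, 11 higher and 4 lower relative to other genes. With an estimated correlation it called 0, and 7 had an unadjusted p under 0.05, while ranked camera called 13. Fry, which tests against no change and not against other genes, called 18.

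**Figure D3:**
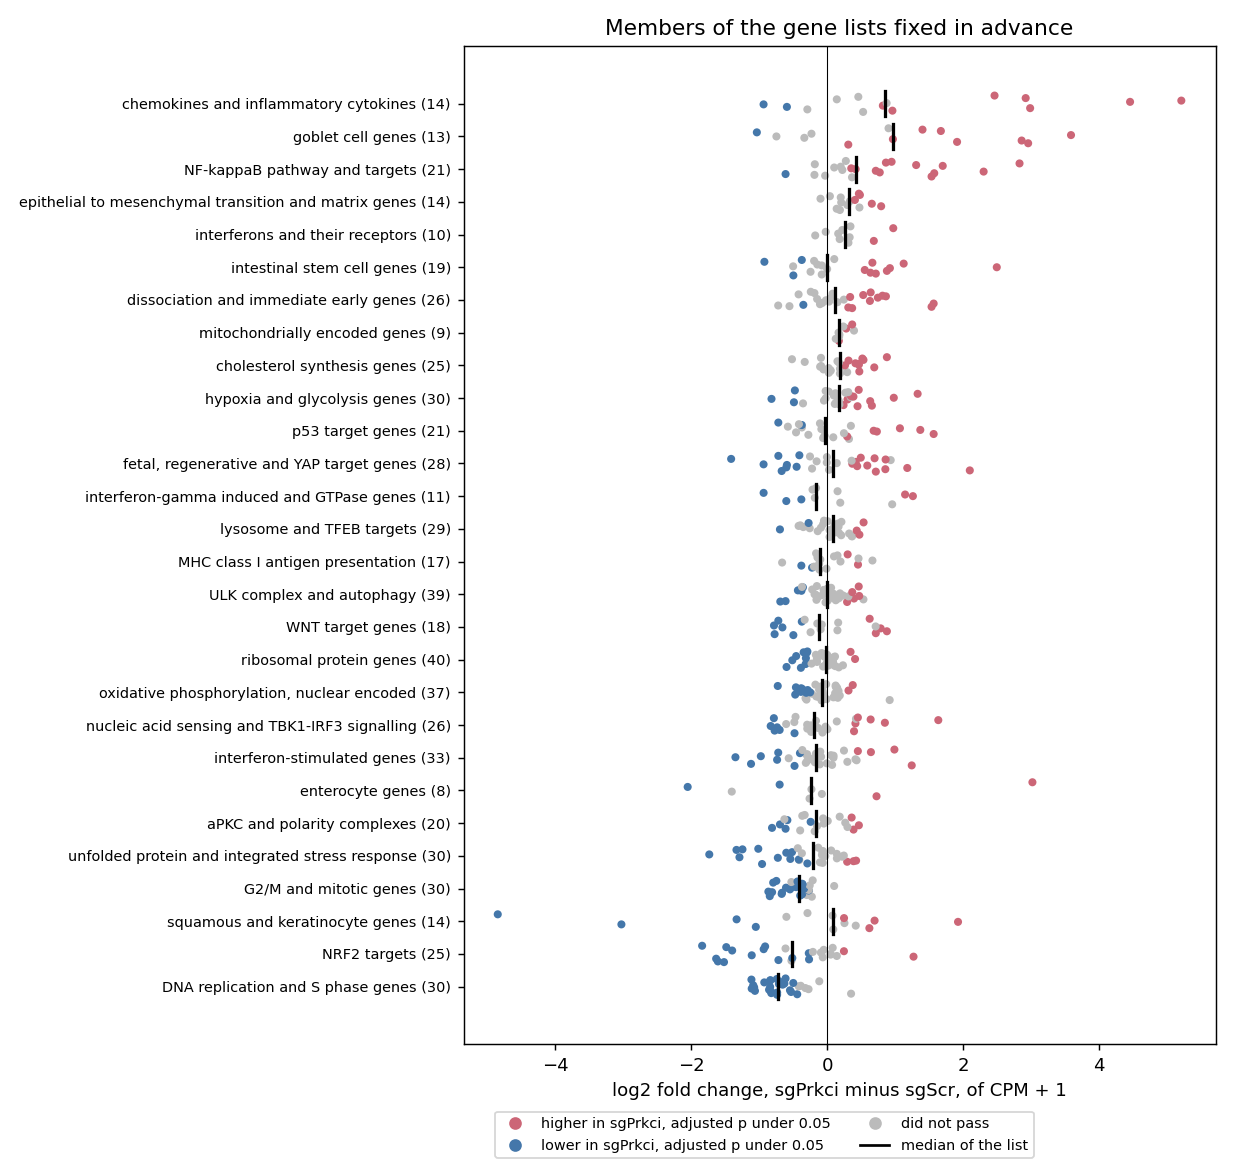
Log2 fold change, sgPrkci minus sgScr, of each tested member of 28 gene lists, 1 point per gene (red higher and blue lower at an adjusted p under 0.05, gray not passing), with a line at the median and the number of members in parentheses. Medians ran from -0.72 for DNA replication to 0.97 for goblet cell genes.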

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

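The count of 3882 changed genes stayed within 1.5 times under every setting fixed in advance except DESeq2 (2540 changed, 1118 lower) and a 2-fold minimum (820 changed, 346 higher, 474 lower), and with chromosome medians removed, an alternative chosen after seeing the data, 1623 genes were lower. The 2-fold minimum keeps fewer genes by construction. Removing chromosome medians also recentres all genes, which by construction accounts for part of its fewer lower genes. The cause of the rest was not tested. Leaving out 1 library gave 2852 to 3794 changed genes, 1091 to 1370 higher and 1758 to 2424 lower, and 13 to 15 called lists. Other such settings gave 2848 (plain moderation) to 4744 (adjusted p under 0.1). The share of higher calls rose from 35.7% to 51.4% with TMM, 51.3% with median-of-ratios, 47.9% with quantile scaling, 51.7% with edgeR, 56.0% with DESeq2 and 49.8% with chromosome medians removed. Of the 3882 calls, 3203 kept their call and direction with TMM, 2382 with DESeq2 and 2796 with chromosome medians removed. Camera with an estimated correlation called 0 lists, and the other settings 13 to 18.

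Prkci did not pass in any setting, with a log2 fold change of 0.042 with TMM, 0.0058 with quantile, 0.042 with median-of-ratios, 0.032 with edgeR and 0.034 with DESeq2, and from -0.17 to 0.052 when 1 library was left out. Irf3 turned to 0.030 (TMM), 0.063 (quantile), 0.030 (median-of-ratios), 0.049 (edgeR), 0.045 (DESeq2) and 0.0087 (chromosome medians removed), and ran from -0.16 to 0.036 when 1 library was left out. With chromosome medians removed Canx turned to 0.18 and Wipi1 to 0.041, neither past the threshold. Among lists, the mean difference from other genes changed sign for interferon-stimulated genes (0.026 with a filter at 5 CPM, 0.017 quantile, 0.0077 edgeR, 0.0063 DESeq2, -0.050 to 0.036 with 1 library left out) and for the list nucleic acid sensing and TBK1-IRF3 signalling (-0.0078 edgeR, -0.011 DESeq2, -0.039 to 0.057 with 1 library left out). It also did for polarity genes (0.0036, chromosome medians removed), enterocyte genes (0.068 with a pseudocount of 5, 0.60 with a filter at 5 CPM, 0.023 quantile, -0.22 to 0.30 with 1 library left out), the list oxidative phosphorylation, nuclear encoded (-0.0015 with a pseudocount of 5, -0.051 quantile) and ribosomal proteins (-0.065 quantile), and the cause was not tested. Of the genes picked by rule, 14 lost their call with DESeq2, 16 with plain moderation, 12 with chromosome medians removed, and 3 to 12 when 1 library was left out. In the simulation at these depths, 4 of 22 changes of 1.5-fold (18.2%) were recovered for genes under 10 CPM and 30 of 45 (66.7%) for genes at 10 CPM or more, a split chosen after seeing the data.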

Other observations

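All gene families and all tests in this part were chosen after the result was seen, except the tests on interferon-stimulated genes below the filter and on other splits of the libraries. Of 20 cytosolic aminoacyl-tRNA synthetase genes, whose enzymes load amino acids onto transfer RNA, 17 fell and 3 did not pass, with a median log2 fold change of -0.62 (camera adjusted p = 2.4e-09, and adjusted p = 0.068 with an estimated correlation). Mars fell from 91.2 ± 8.88 to 42.9 ± 5.95 CPM, Tars from 244 ± 24.1 to 117 ± 5.17 CPM and Rars from 412 ± 29.3 to 212 ± 12 CPM. Of 33 translation initiation and elongation factor genes 20 fell (camera adjusted p = 1.9e-05, and adjusted p = 0.15 with an estimated correlation), such as Eif3d, from 112 ± 3.67 to 68.8 ± 2.07 CPM, and Eif2s2, from 1525 ± 74 to 955 ± 10.1 CPM. Of 31 proteasome subunit genes 15 fell and 1 rose (camera adjusted p = 0.00094, and adjusted p = 0.21 with an estimated correlation), with Psmb3 going from 105 ± 34.3 to 54.1 ± 11.7 CPM. With chromosome medians removed 14 synthetase, 15 translation factor and 8 proteasome genes fell.

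Of 17 annexin and S100 genes 7 rose and the other 10 did not pass (camera adjusted p = 0.0003, and adjusted p = 0.068 with an estimated correlation), with Anxa4 going from 590.1 ± 21.5 to 1300.4 ± 49.8 CPM. Of 24 junction genes 7 rose and 5 fell (camera adjusted p = 0.023, and adjusted p = 0.15 with an estimated correlation): Cdh17, an intestinal cadherin gene, rose from 75.4 ± 9.8 to 497 ± 39.6 CPM and the claudin gene Cldn2 from 79.2 ± 6.27 to 403 ± 53.1 CPM, and Cgnl1 fell from 360.3 ± 32.5 to 137 ± 18.1 CPM. Of 26 genes of the TGF-beta and BMP pathway 4 rose and 5 fell (camera adjusted p = 0.69, and 0.75 with an estimated correlation). The ligand gene Bmp4 fell from 132 ± 16.7 to 15.7 ± 4.85 CPM, and the target genes Id3 from 81.1 ± 10.7 to 23.2 ± 2.83 CPM and Id1 from 194 ± 13.3 to 109 ± 5.4 CPM, while the ligand gene Bmp2 rose from 19.98 ± 3.03 to 53.3 ± 9.89 CPM. Of 17 genes of the EGF receptor family, its ligands and targets 6 rose and 3 fell (adjusted p = 0.095, 0.21 with an estimated correlation and 0.017 with chromosome medians removed), and the ligand gene Tgfa rose from 52.6 ± 8.51 to 101 ± 7.55 CPM. Of 10 integrin genes 3 rose and 2 fell (adjusted p = 0.11, 0.21 with an estimated correlation and 0.0051 with chromosome medians removed), of 15 Notch pathway genes 1 rose and 2 fell (adjusted p = 0.69, and 0.78 with an estimated correlation) and of 22 TNF and IL-1 receptor signalling genes 4 rose and 4 fell (adjusted p = 0.69, and 0.75 with an estimated correlation).

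Genes of chromosomes 8, 11 and 15 were lower in sgPrkci as a body. After a correction for GC content, transcript length and expression level in each library the chromosome 11 shift was -0.307 (SE 0.0083), so these trends did not give it there. Without genes that changed at least 2-fold it was -0.289 (SE 0.0077), but a median is little moved by a few genes, so that check could hardly come out otherwise. Of its 647 genes at a mean of at least 10 CPM, 83.0% lay below the median of all genes, more than a few strong genes would give. Both checks covered chromosome 11 alone. All 20 windows of 20 Mb on the 3 chromosomes, which were picked for being lower, lay below the median of all genes, as a difference in chromosome number between the organoid populations would give, perhaps in part of their cells. The windows of chromosomes 10 and 18 all lay below it too, and windows within a chromosome were uneven, from -0.45 to -0.13 on chromosome 8, 0.052 to 0.56 on chromosome 4 and -0.27 to 0.23 on chromosome 7. Ulk2 minus the chromosome 11 median was -0.291 (SE 0.175), within 2 SE of 0, so its fall may be part of that shift, and no DNA was analysed here, nor whether a difference arose with the guide or as the lines diverged.

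The Y-linked genes had 1 read in sgScr and 336 in sgPrkci, a level in sgScr of 0.256% of that in sgPrkci (exact 95% interval 0.00646 to 1.43%). An exchange of part of the libraries is argued against by Pearson's r without Y-linked genes, at least 0.981 within and at most 0.954 between groups, with 0 libraries closer to the other group, but an exchange of the whole groups stays open. Xist, which silences an X chromosome in female cells, reached at most 0.670 CPM in sgScr, and the chromosome X shift was 0.0721 (SE 0.0058). These values argue against female cells in sgScr with an X silenced by Xist or with a pair of active X chromosomes. They do not decide the sex of origin of the sgScr cells. Loss of the Y chromosome from the sgScr population, or reads of a different male line in sgPrkci, may give the Y-linked difference, and neither was tested.

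Interferon-stimulated genes did not pass as a list. The 24 members below the filter showed no summed rise, with 74 summed reads in sgScr and 36 in sgPrkci. Their ratio by depth was 0.566 (95% counting interval 0.369 to 0.854). However, an exact two-sided permutation test gave p = 0.2, where 0.1 is the smallest that 3 against 3 libraries allow. A member at 1 CPM or more in all 3 sgPrkci libraries passes the filter, so these 24 could not hold a rise to that level. With the chromosome medians removed, the mean difference of the tested list from other genes was -0.0241 (camera adjusted p = 0.82). But 3 tested members rose and 4 fell there, so whether chromosome shifts hide a rise stays open. A response at another time, in treated organoids or at the protein level stays open, as untested here.

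The 6 libraries in 2 groups of 3 make 10 splits, too few for a share under 0.05. The real split gave 3882 changed genes and the highest of the others 0, the real split 15 called lists and the highest other 8, and the real split 7 called chromosomes and the highest other 3, and 1 of the 10 splits, the real one, gave as many in each case. Every other split mixed libraries of both groups, so the group difference widened its spread and favoured low gene counts by construction. No conclusion on chance is drawn from these counts.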
